A study of Drosophila melanogaster with 12 samples.

How the data were processed

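Gene expression was profiled by RNA sequencing of Drosophila melanogaster larval carcass, the muscle and epidermis that remain once the gut has been dissected out. The 12 libraries form 4 groups of 3, all from foraging larvae late in the last larval instar. The smox group carried a mutant allele of Smox, the Smad transcription factor of the Activin branch of TGF-beta signaling, over the Y chromosome, so its larvae were male by genotype. Its reference was w1118, a white-eyed laboratory stock taken as wild type, whose sex is not given in the sources used here. Both were fed yeast paste on apple juice plates and had no further treatment. The MhcGal4>baboACT group expressed an activated form of Baboon, the Activin receptor that phosphorylates Smox, from the muscle driver MhcGal4. Its reference carried MhcGal4 without the receptor. Both genotypes also carried temperature-sensitive Gal80, an inhibitor of Gal4, ate standard vial food and spent the final 12 h before RNA isolation at 30 °C. Per the labels' protocols, RNA was isolated with TRIzol, cleaned on columns and made into libraries with a TruSeq RNA kit. Whether the kit marked the strand, the aligner, the annotation, the genome build and the read numbers are not given in the sources used here.

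The submitters' processing notes name Cufflinks and Cuffdiff, without versions. There is 1 table per experiment, each with 13650 rows, and 0 columns hold single libraries. Per the file headers, each row gives 1 FPKM for each of both groups, a fragment count scaled by transcript length and by mapped fragments. The authors also deposited a test statistic, which is a score with no fixed range, and a p-value with its adjusted q-value. A further deposited column holds the authors' log2 fold change, in which spreadsheet error text stands in 423 cells of the smox table and 480 cells of the baboACT table. How the authors pooled 3 libraries into 1 FPKM, and how they scaled the libraries, is not given in the sources used here. The lowest p in either table was 5e-05, so genes below that cannot be ranked by it.

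No spread between libraries can be computed from group values, so no SD, n or test of the difference between libraries stands beside any FPKM here. The limma test and the camera test of gene lists chosen before the data were examined need values per library and were not run. The design written at that time foresaw this case, and the authors' deposited values are described in their place. A gene is said to have been called, to have risen or to have fallen where its q was under 0.05 in the authors' deposited table. The labels do not say that the libraries of a group came from separate animals, so these q-values may measure technical spread in part.

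Fold changes were computed from the authors' FPKM as the ratio of the mutant or expressing group to its reference, on the log2 scale with no pseudocount. They differed from the authors' log2 fold change by at most 0.04 in smox and 0.0041 in baboACT over rows with a mean FPKM of at least 1. Counts and gene lists used the rows that the authors tested, with FPKM above 0 in both groups, a mean FPKM of at least 1 and a gene name that occurs once. This left 7977 genes in smox and 8018 in baboACT. An FPKM of exactly 0 can be a failed estimate. Mhc and Mlc2, among the most abundant muscle transcripts, are each listed at 0 in 1 or more groups, so such rows are given as listed and without a fold. A further 366 rows per experiment name more than 1 gene. Reads of these overlapping genes cannot be told apart, and such rows are printed with all their names. Of 14054 gene names in the tables, 10567 matched a current symbol of the reference annotation and a further 3223 matched through 1 synonym.

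Coordinates come from the authors' tables, whose build is not named. Starts there count from 0, so 1 was added to each start printed, and ends are unchanged. The most common difference between gene ends in the tables and in the BDGP6 annotation was -4112495 bases on 2R, shared by 417 of 1992 genes, and -105967 on X, shared by 337 of 1623. The tables therefore use another build, and BDGP6 served for names only.

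Depth is not known from FPKM. Low values were compared with whole multiples of 1 fragment over locus length, and between 25.7% and 32.1% of them came within 10% of a unit of a multiple, where chance gives 20%, so no depth could be recovered. Summed over all rows, FPKM came to 962767 in w1118, 964492 in smox, 755064 in MhcGal4 and 812782 in baboACT. The 10 highest rows held 32.4%, 34.8%, 17.2% and 20.6% of these sums, in that order.

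Each of 29 gene lists, fixed before the data were examined from general knowledge of fly genes, was described by the median log2 fold change of its measured members. That median was placed among the medians of 10000 random lists of equal size, matched on mean FPKM in 20 bins. A list below percentile 2.5 or above 97.5 is called outside. The percentile describes these values and is not a test between genotypes, and genes that share regulation stray further than random genes. Of 29 lists, 1.45 would lie outside by chance. For simulated data, the observed fold changes were shuffled over all genes and 20 genes were drawn at random. Each such list was set against fewer random lists than the 10000 above. With no shift they lay outside in 8 of 100 draws over the smox genes and 5 of 100 over the baboACT genes. With a shift of 0.2 on the log2 scale the counts were 45 and 60 of 100, and with a shift of 0.5 they were 100 and 100. Shuffling removes any tie of fold change to FPKM and among members of a list. These rates therefore do not carry over to lists of genes that share regulation. Members called are counted over all genes the authors tested and, where the count differs, adjusted over the list alone by the Benjamini-Hochberg method.

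The genes named follow a rule fixed at the same time. It takes Smox, babo and w, the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean FPKM of at least 5, 4 members of each list outside, ordered by q and then by size of fold, and the preset genes Mhc, GluRIIA, GluRIIB, InR, Thor, Hex-A, Pfk, Ldh, EcR, roX1 and roX2. It also takes the 10 genes called in opposite directions in both comparisons whose smaller fold was largest. The part of the rule that asked for no overlap between libraries could not be applied. Other genes named, among them all members of lists that lay inside the random range, were chosen after their values were seen, as were the lists of glue, other salivary gland and pigmentation genes.

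Alternatives were a pseudocount of 0.1 or 1, no filter on low values or a mean FPKM of at least 5, median-ratio scaling, quantile normalization, other thresholds and, for X-linked genes, scaling to the autosomes. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.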

Results

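Transcript levels were measured in the body wall of foraging larvae in 4 groups of 3 libraries each. One experiment set smox mutant larvae against w1118 larvae and asked which transcripts depend on Smox, the Smad protein that carries Activin signals to the nucleus. The other set larvae with activated Baboon in muscle against MhcGal4 larvae and asked which transcripts respond when the Activin receptor is switched on for 12 h. The deposited tables hold 1 FPKM per gene and group, so no value below has a spread between libraries, and read depth is unknown. The experiments differ in food, temperature, genetic background, and the tissue and duration of the genetic change. They were tabulated separately, so levels are compared only within an experiment. Statements that a gene rose, fell or was called rest on a q under 0.05 in the authors' deposited table. Where no q is printed, it was 0.000152 in the smox table and 0.000217 in the baboACT table, the values that go with the lowest p there.

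The targeted genes were read first. Smox, on the X chromosome from 8032424 to 8036301 in the coordinates of the tables (build not named), fell from 23.9 FPKM in w1118 to 1.40 FPKM in smox, a log2 fold change of -4.10. The sequence change of the allele is not given in the sources used here. In the other experiment Smox stood at 29.8 FPKM in MhcGal4 and 32.5 FPKM with activated Baboon (q = 0.139 in the authors' deposited table). The receptor gene babo, on 2R from 4839846 to 4850301, rose from 13.2 to 15.6 FPKM with activated Baboon, a log2 fold change of 0.23 (q = 0.00424 in the authors' deposited table). It fell from 14.7 to 12.6 FPKM in smox, a log2 fold change of -0.22 (q = 0.000558 in the authors' deposited table). Whether reads from the transgene count toward babo is not given in the sources used here, so the small rise of babo with activated Baboon does not show how strongly the transgene was expressed. The eye-color gene w, which also marks transgenes, was listed at 0.0159 FPKM in w1118 and 0.263 FPKM in smox, where it was not tested. It fell from 2.42 to 1.60 FPKM with activated Baboon (log2 fold change -0.59, q = 0.00323 in the authors' deposited table).

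In smox carcasses, transcripts of the proteasome, of several glutamate receptor subunits of the neuromuscular synapse and of salivary glue were lower than in w1118. Transcripts of fat body storage proteins, of many detoxifying enzymes and of the translational repressor Thor were higher. Of 7977 genes measured, 4638 were called, 1466 of them higher and 3172 lower (68.4% lower). The typical change was small, with a median of 1.36-fold among called genes, and 725 genes changed by at least 1 on the log2 scale, 357 up and 368 down. The median gene lay at -0.14 on the log2 scale, a shift that median-ratio scaling would remove, and gene lists are therefore placed against random lists from the same genes.

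The largest rises in smox were in CG2070, from 0.107 to 78.5 FPKM (log2 fold change 9.52), and in e, which encodes the beta-alanyl-dopamine synthase of cuticle tanning, from 0.447 to 232 FPKM (9.02). They were followed by CG34244, CG7906, CG7924, CG34193, the drosomycin-like gene dro5, Cyp304a1, ple, which encodes tyrosine hydroxylase, and CG13606. CG2070 and dro5 each had q = 0.00585 in the authors' deposited table. CG34244, CG7906 and CG7924 start on 3L at positions 14228283, 14229824 and 14226569 and went from under 2 FPKM to 723, 683 and 706 FPKM. The largest fall was in CG17105, on 2L from 10681047 to 10681358, from 21169 to 58.7 FPKM (log2 fold change -8.49). CG10910, CG13324, CG7587, CG11854, Ag5r2, CG31698, Sgs8, Sgs3 and Smox itself followed, among which CG11854 went from 1865 to 71.4 FPKM. Folds of genes with little signal in one group depend on that low value: with a pseudocount of 1, the log2 fold change of CG2070 in smox was 6.17 and that of e in smox was 7.33.

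Muscle and synapse genes did not move as a block in smox. Of 21 measured genes of the postsynaptic list, 3 rose and 10 fell, and the list median (-0.12) lay inside the range of matched random lists. Among those that fell were both alternative subunits of the glutamate receptor. The row CG14017,GluRIIA, on 2L from 5553897 to 5558994, where reads of the overlapping genes cannot be told apart, went from 18.8 to 6.44 FPKM (log2 fold change -1.55). GluRIIB, its neighbor from 5559342 to 5563502, went from 7.90 to 3.06 FPKM (-1.37). The row GluRIIE,KaiRIA, where reads of the genes named cannot be told apart either, fell from 69.7 to 29.8 FPKM. The potassium channel gene Sh fell from 4.22 to 1.85 FPKM. GluRIIC, a further subunit of the receptor, stood at 27.5 and 25.2 FPKM and was not called (q = 0.108 in the authors' deposited table). Of 26 sarcomere genes 10 rose and 9 fell, with the giant structural genes sls and Msp-300 among the rises (log2 fold changes of 0.67 and 0.99) and TpnC73F among the falls (-0.43). Mlc1 was at 6814 and 6861 FPKM and was not called. Mhc is listed at 2892 FPKM in w1118 and at 0 in smox, a pair of values from which no fold is drawn. The list of muscle identity and attachment genes lay outside on the high side, with 9 of 19 members up and 2 down. Its median was 0.15, and Scgdelta of the sarcoglycan complex rose from 13.9 to 22.2 FPKM, the perlecan gene trol from 8.29 to 13.3, sr from 6.22 to 9.61 and rst from 4.68 to 6.89.

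**Figure D1:**
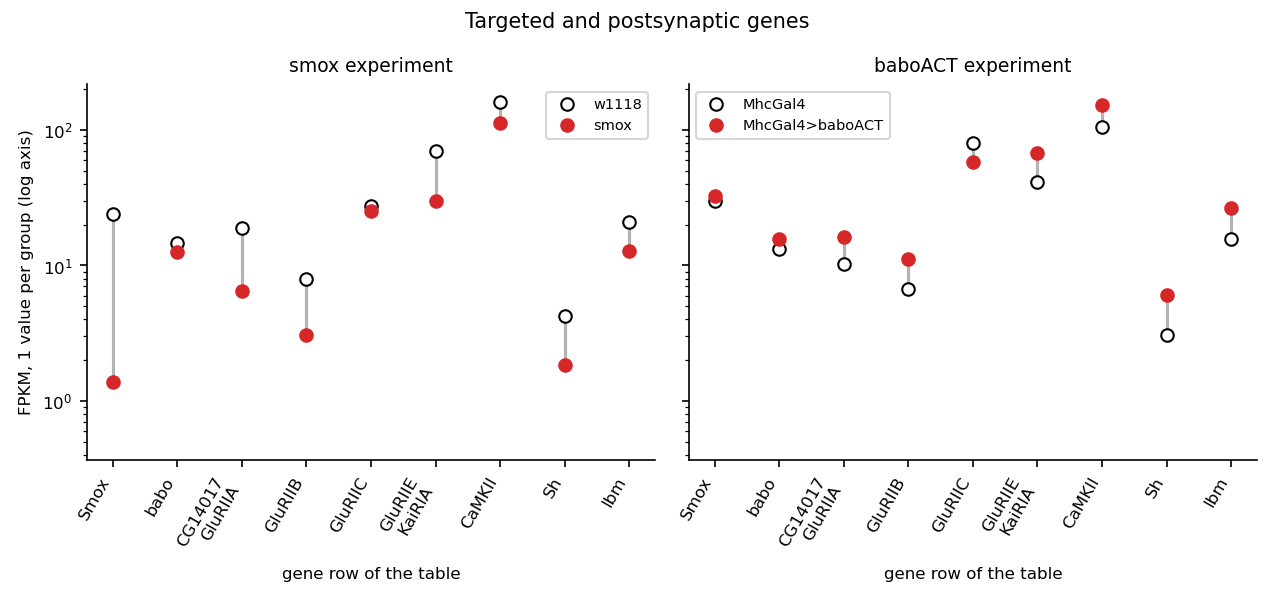
FPKM on a log axis of the targeted genes and of 7 postsynaptic genes, 1 open point for each reference group and 1 filled point for smox (left) or activated Baboon (right). Points are the authors' group values and carry no error bars. The rows CG14017,GluRIIA and GluRIIE,KaiRIA, each naming more than 1 gene, and the rows GluRIIB and Sh lie lower in smox than in w1118. The same rows lie higher with activated Baboon than in MhcGal4.

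The proteasome list was lower as a whole in smox. All 32 measured genes fell, with a median log2 fold change of -0.92 and single genes between -2.01 and -0.59. Rpt4, an ATPase of the regulatory particle, went from 203 to 87.6 FPKM and Rpn9 from 220 to 105 FPKM. CG17331, a core particle gene, fell from 363 to 161 FPKM and Rpt6R from 5.34 to 1.33 FPKM. The middle 95% of random lists of that size and expression reached only from -0.28 to 0.03.

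Hormone-responsive and cuticle genes changed in both directions in smox. Of 28 ecdysone and juvenile hormone genes, 15 fell and 8 rose, and the median of -0.34 was outside on the low side. That list holds glue genes, 5 of which were measured. Without them 10 of 23 genes fell and 8 rose, and the median of 0.01 lay inside the random range, at percentile 94.1. EcR, the ecdysone receptor gene, fell from 49.7 to 23 FPKM (log2 fold change -1.11), while Eip78C rose from 0.846 to 15.9 FPKM (4.23). The glue genes Sgs8, Sgs3 and Sgs4, normally active in salivary glands before pupation, fell from 71.4 to 3.48, from 120 to 5.97 and from 16.6 to 1.17 FPKM. Cuticle protein genes went 24 up and 24 down among 58 measured (24 and 25 adjusted over the list alone). Cpr100A rose from 1.63 to 11.8 FPKM, while Cpr67Fa2 fell from 841 to 62.3, Cpr49Ad from 30.7 to 2.47 and Lcp65Ag3 from 176 to 23.4 FPKM. That list's median of 0.12 was outside on the high side, against a range of -0.18 to 0.02.

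Fat body, lipid and detoxification lists had medians outside on the high side in smox. The amount of fat body in the carcasses was not measured, so tissue amount and expression cannot be told apart for its markers. The fat body list, markers of the storage tissue that lines the body wall, had 8 of 12 members up and 4 down, with a median of 0.89. Its storage protein genes Lsp2 (190 to 527 FPKM) and Lsp1gamma (235 to 626 FPKM) rose, as did Rfabg, the lipophorin gene (12.3 to 29.3 FPKM), while fat-spondin fell (16.6 to 6.19 FPKM). Lipid metabolism genes had 14 of 21 members up and 3 down (15 and 3 adjusted over the list alone), with a median of 0.35. The fatty acid synthase row CG3523 rose from 16.7 to 35.9 FPKM, Fatp from 35.2 to 55.1, v(2)k05816 from 15.0 to 25.0 and Lip4 from 1.05 to 3.97. Of 46 cytochrome P450 genes 27 rose and 8 fell (30 and 10 adjusted over the list alone), with a median of 0.66. Cyp6a2 went from 0.901 to 10.1 FPKM, Cyp6d2 from 1.13 to 11.2, Cyp304a1 from 1.12 to 169 and Cyp18a1, which inactivates ecdysone, from 6.57 to 48.0. Of 27 glutathione transferase genes 15 rose and 9 fell, with a median of 0.47, and GstE7 rose from 12.2 to 70.2 FPKM, GstD10 from 12.7 to 55.8, GstE6 from 30.4 to 59.3 and CG1681 from 78.2 to 175.

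Immune and gut transcripts were also outside in smox. The immune list had a median of 0.78, though only 5 of 18 members rose and 2 fell. PGRP-SA rose from 37.4 to 83.3 FPKM and Dro from 36.5 to 64.2, whereas Listericin fell from 507 to 53.1 and TotA from 23.5 to 3.09. Midgut genes fell in 8 of 11 cases and rose in 0, with a median of -3.0. The serine protease genes Jon65Aiii (83.6 to 7.75 FPKM), Jon65Aiv (198 to 23.2), Jon25Bi (78.4 to 9.96) and Jon25Bii (56.8 to 11.1) were among them. The gut had been removed from all carcasses, and how much of it remained in each group was not measured. For midgut genes, unequal remains of gut and a change in expression cannot be told apart.

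Signaling genes gave mixed values in smox. In the TGF-beta list 5 of 18 members rose and 9 fell (5 and 10 adjusted over the list alone), and its median was inside. The Activin ligand gene daw rose from 2.24 to 18.0 FPKM (log2 fold change 3.01), whereas the BMP receptor gene tkv fell from 29.2 to 13.4 FPKM. Of 29 insulin and TOR genes 8 rose and 12 fell (9 and 13 adjusted over the list alone), inside the random range. Thor, the 4E-BP gene, rose from 681 to 1683 FPKM (log2 fold change 1.31), and InR, the insulin receptor gene, from 2.59 to 3.20 FPKM (0.31). ImpL2, an inhibitor of insulin signaling, fell from 192 to 86.2 FPKM. Glycolysis genes went 4 up and 9 down among 20. ImpL3, the lactate dehydrogenase gene, rose from 1151 to 1442 FPKM (log2 fold change 0.33), while Hex-A (45.5 and 41.7 FPKM, q = 0.0832) and Pfk (308 and 329 FPKM, q = 0.173) were not called in the authors' deposited table.

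The other lists lay inside the random range in smox. Members of the oxidative phosphorylation list went 4 up and 20 down among 68 (4 and 19 adjusted over the list alone), and those of the TCA cycle 5 up and 3 down among 19. Cytosolic ribosomal proteins went 5 up and 12 down among 84 (3 and 3 adjusted over the list alone), and ribosome biogenesis 2 up and 10 down among 20. The 2 that rose were pes and bor, which entered that list by symbol although these fly genes are not known for ribosome biogenesis. Proliferation genes went 0 up and 17 down among 25. The autophagy list went 3 up and 7 down among 21, and amino acid metabolism 10 up and 8 down among 23. Heat shock genes went 9 up and 7 down among 22 (9 and 8 adjusted over the list alone), and hemocyte genes 7 up and 8 down among 21 (7 and 9 adjusted over the list alone). Ion channels went 6 up and 8 down among 19 (6 and 10 adjusted over the list alone), and nervous system genes 2 up and 2 down among 10 (1 and 1 adjusted over the list alone). Tracheal genes went 3 up and 4 down among 13, sex and dosage compensation genes 3 up and 4 down among 10, and testis genes 1 up and 1 down among 3.

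With activated Baboon in muscle, proteasome and glue transcripts and many heat shock, ecdysone-response and cuticle transcripts were higher than in MhcGal4. Most transcripts of mitochondrial respiration and ribosomes and many of hemocytes were lower. Of 8018 genes measured, 3512 were called, 2330 higher and 1182 lower (66.3% higher). The median change among called genes was 1.35-fold, and 506 genes changed by at least 1 on the log2 scale, 367 up and 139 down. The median gene lay at 0.08.

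The largest rises were in CG7587, from 1.70 to 124 FPKM (log2 fold change 6.19), CG17386 (6.18), CG13856 (5.74, q = 0.0079 in the authors' deposited table), CG2444, CG13947, CG3502, the nuclear receptor gene Eip78C and the glue genes Sgs1, Sgs7 and Sgs8. CG2444, on the X chromosome from 11589145 to 11599044, went from 61.2 to 3172 FPKM. The largest falls were in CG15236, from 14.5 to 0.125 FPKM (log2 fold change -6.86), CG10912 (-5.73), CG9568 (-5.46), CG15829, CG14075, CG32302, CG13324, CG32212, CG5399 and the antifungal peptide gene Drs (q = 0.01 in the authors' deposited table). With a pseudocount of 1, the log2 fold change of CG15236 in baboACT was -3.79.

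All 33 measured proteasome genes rose with activated Baboon, by a median of 0.63 on the log2 scale and by 0.45 to 3.79 in single genes. Rpt6R went from 0.654 to 9.05 FPKM, Rpn3 from 112 to 204, Rpt4 from 136 to 243 and Rpn9 from 170 to 288. Of 22 heat shock and chaperone genes 15 rose and 2 fell (15 and 3 adjusted over the list alone), with a median of 0.53. Hsp67Bc rose from 0.429 to 5.57 FPKM, Hsp26 from 14.6 to 121, Hsp23 from 71.6 to 502 and Hsp27 from 40.9 to 216. Both groups had spent the same 12 h at 30 °C.

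Ecdysone and cuticle lists had medians outside on the high side with activated Baboon. In the ecdysone and juvenile hormone list 19 of 29 members rose and 2 fell (20 and 2 adjusted over the list alone), with a median of 0.85. Without its 6 measured glue genes 13 of 23 rose and 2 fell (14 and 2 adjusted over the list alone), and the median of 0.49 was still outside. EcR rose from 34.9 to 49.6 FPKM (log2 fold change 0.51) and Eip78C from 0.594 to 28.1 FPKM (5.56). Sgs7 rose from 26.7 to 1105 FPKM, Sgs8 from 5.59 to 222 and Sgs1 from 0.434 to 21.7. Of 56 cuticle protein genes 29 rose and 7 fell (30 and 7 adjusted over the list alone), with a median of 0.48. TwdlP went from 1.36 to 47.6 FPKM, Cpr49Ac from 242 to 4041, Lcp65Ag1 from 27.8 to 405 and Cpr47Eg from 139 to 1831.

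Lists for respiration, the TCA cycle, ribosomes, their biogenesis and proliferation had medians outside on the low side with activated Baboon, by small amounts. In the oxidative phosphorylation list 53 of 68 members fell and 1 rose, with a median of -0.34. CG3731 of complex III went from 428 to 277 FPKM, the ATP synthase gene Oscp from 594 to 389, RFeSP from 315 to 214 and ND75 from 188 to 129. Of 19 TCA cycle genes 13 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.37. The fumarase row CG4095,l(1)G0255 fell from 347 to 199 FPKM, the citrate synthase gene kdn from 376 to 254 and l(1)G0156 from 409 to 276, while the pyruvate carboxylase gene CG1516 rose from 39.4 to 97.4. Cytosolic ribosomal protein genes fell in 74 of 84 cases and rose in 0 (75 and 0 adjusted over the list alone), with a median of -0.32. Among them RpL8 went from 1793 to 1270 FPKM, RpS7 from 3076 to 2198, RpL35A from 1029 to 736 and RpL24-like from 193 to 139. Under quantile normalization this list was inside the random range, at -0.050 from the random median. Ribosome biogenesis genes fell in 11 of 20 cases and rose in 0 (13 and 0 adjusted over the list alone), with a median of -0.31. Examples were nop5 (25.3 to 18.6 FPKM) and the fibrillarin gene Fib (23 to 16.9). The 11 also include pes (3.64 to 1.93 FPKM) and bor (18.9 to 11.9), which entered the list by symbol although these fly genes are not known for ribosome biogenesis. Proliferation genes fell in 7 of 25 cases and rose in 0 (4 and 0 adjusted over the list alone), with a median of -0.18, among them nub (2.20 to 1.26 FPKM), Mcm6 (9.79 to 7.65, q = 0.000411), polo (10.4 to 8.18, q = 0.00261) and stg (4.42 to 3.49, q = 0.0128), with q from the authors' deposited table.

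Hemocyte, midgut, immune and cytochrome P450 lists had medians outside on the low side with activated Baboon, though few immune genes were called. Of 21 hemocyte genes 12 fell and 5 rose, with a median of -0.39. The genes nimB1 (7.72 to 3.96 FPKM), nimB4 (23.1 to 12.0) and CG8193 (92.3 to 58.4) fell, and Ance rose from 38.9 to 157 FPKM. Midgut genes fell in 8 of 15 cases and rose in 0, with a median of -1.28, among them Bace (10.6 to 1.16 FPKM), LysS (72.9 to 15.0), Jon65Aiii (169 to 35.3) and Jon65Aiv (197 to 76.8). The amounts of hemocytes and of gut left in these carcasses were not measured either. The immune list had 4 of 22 members down and 2 up (4 and 1 adjusted over the list alone), with a median of -0.73. Drs went from 11.7 to 0.982 FPKM, AttA from 9.56 to 2.5 and Dro from 61.3 to 20.7, while dro5 rose from 6.75 to 121 FPKM. Cytochrome P450 genes fell in 23 of 48 cases and rose in 10, with a median of -0.34. Cyp6a2 fell from 8.13 to 1.07 FPKM, Cyp4e3 from 4.03 to 0.575 and Cyp6d2 from 4.77 to 0.854, and Cyp6a13 rose from 2.15 to 8.37.

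Synaptic and signaling lists lay inside the random range with activated Baboon. Of 22 postsynaptic genes 9 rose and 3 fell. The row CG14017,GluRIIA rose from 10.3 to 16.3 FPKM (log2 fold change 0.66) and GluRIIB from 6.71 to 11.1 FPKM (0.73), while GluRIIC fell from 80.0 to 58.1 FPKM (-0.46). The row GluRIIE,KaiRIA rose from 41.3 to 67.7 FPKM (q = 0.0061 in the authors' deposited table), and Sh from 3.09 to 6.03 FPKM. In the TGF-beta list 6 of 18 members rose and 1 fell, the one that fell being daw (26 to 13.9 FPKM, log2 fold change -0.91). Of 29 insulin and TOR genes 11 rose and 6 fell (11 and 7 adjusted over the list alone). InR fell from 4.58 to 3.78 FPKM (log2 fold change -0.28, q = 0.00496 in the authors' deposited table) and Thor from 1244 to 1082 FPKM (-0.20, q = 0.0397). Glycolysis genes went 4 up and 7 down among 20. Hex-A rose from 47.1 to 60.2 FPKM (log2 fold change 0.36), while Pfk (206 and 206 FPKM) and ImpL3 (768 and 773 FPKM) were not called, with q of 0.982 and 0.947 in the authors' deposited table. Of 25 sarcomere genes 5 rose and 13 fell (5 and 14 adjusted over the list alone), the myosin light chain gene Mlc1 going from 8429 to 6081 FPKM. Mhc and Mlc2 are listed at 0 in MhcGal4 and at 3350 and 10733 FPKM with activated Baboon, and no fold is drawn from them.

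In the same experiment muscle identity genes went 6 up and 3 down among 19, and autophagy genes 9 up and 1 down among 21. The lipid list went 2 up and 5 down among 21, amino acid metabolism 6 up and 7 down among 22, and fat body 4 up and 5 down among 12. Glutathione transferases went 9 up and 3 down among 24 (10 and 3 adjusted over the list alone), and ion channels 6 up and 3 down among 20. Tracheal genes went 5 up and 1 down among 13 (7 and 1 adjusted over the list alone), and nervous system genes 1 up and 2 down among 11. Sex and dosage compensation genes went 1 up and 2 down among 10, and testis genes 0 up and 1 down among 4 (0 and 2 adjusted over the list alone). All of these lists were inside the random range.

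**Figure D2:**
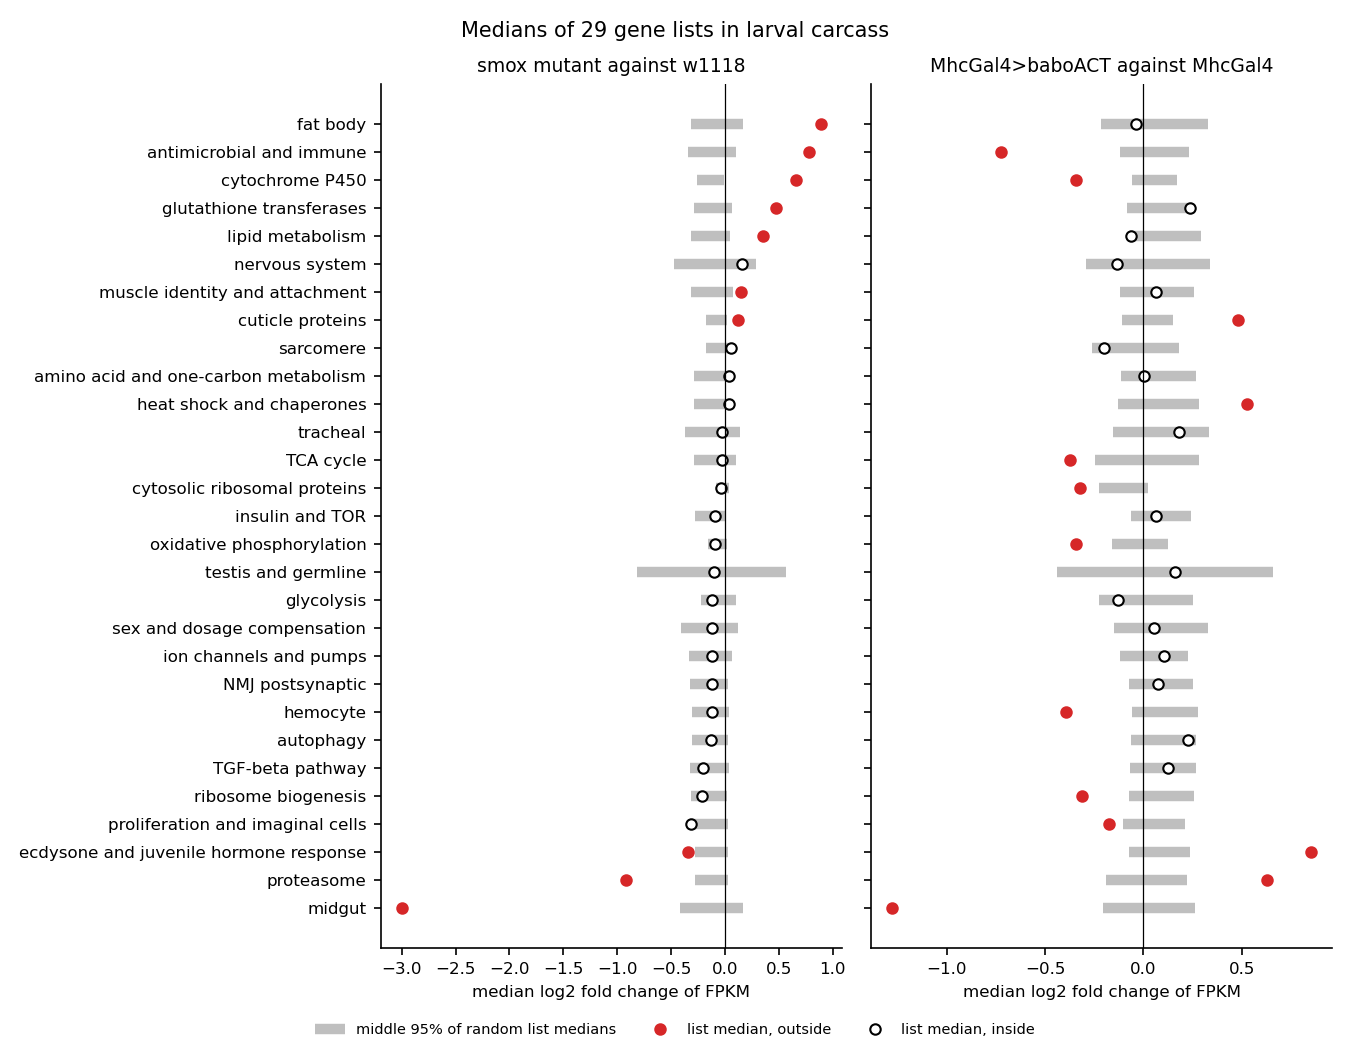
Median log2 fold change of FPKM in each of 29 gene lists, for smox against w1118 (left) and activated Baboon against MhcGal4 (right), with horizontal axes of different length. Gray bars span the middle 95% of medians of matched random lists, filled points are list medians outside that span (10 in smox, 13 with activated Baboon) and open points are those inside. The proteasome median is -0.92 on the left and 0.63 on the right.

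One experiment lowers the Smad of the Activin pathway and the other activates its receptor, so genes that answer to the pathway would be predicted to move in opposite directions. The smox mutation was not limited to a tissue or a time, while the receptor was driven in muscle for 12 h. An opposite change therefore need not be a direct response. Of 7768 genes measured in both, 2429 were called in both, and 1938 of these (79.8%) moved in opposite directions. Of the opposite genes, 1504 were lower in smox and higher with activated Baboon and 434 were the reverse, while 263 genes were higher in both and 228 lower in both. Lists drawn independently would give 1128 opposite and 871 concordant genes. The odds ratio of opposite directions among genes called in both was 10.9 (Fisher's exact test, two-sided p = 2.4e-126, which treats genes as independent although they are not). Of 217 genes that changed by at least 1 on the log2 scale in both, 153 (70.5%) were opposite. No library is shared between the experiments. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of -0.23 and a Spearman rho of -0.37, and over 5528 genes called in at least 1 comparison r was -0.22 and rho -0.37.

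The genes with the largest opposite changes were CG7587, CG12715, CG13856, CG12539 and the glue and salivary genes Sgs8, Sgs3, Sgs4, Sgs7, Sgs5 and Eig71Ee, all lower in smox and higher with activated Baboon. CG12715 had q = 0.00901 in the authors' deposited table for smox. CG7587 and Sgs5 are neighbors on 3R. CG7587 fell from 156.5 to 4.49 FPKM in smox and rose from 1.70 to 124 FPKM with activated Baboon. Sgs3 fell from 120 to 5.97 FPKM and rose from 9.15 to 359 FPKM. Of the 29 lists, 10 were outside in smox and 13 with activated Baboon. The 6 outside in both included 4 whose medians moved in opposite directions, namely proteasome, ecdysone and juvenile hormone, cytochrome P450 and immune genes. Without its glue genes the ecdysone list was outside only with activated Baboon. The cuticle protein median was outside on the high side in both experiments, and the midgut median on the low side in both. Single cuticle genes did not all move alike, and in smox 24 rose and 24 fell. Cpr67Fa2, Cpr49Ad, Lcp65Ag3 and Cpr49Ac fell in smox and rose with activated Baboon, and Cpr100A did the reverse. Cpr47Eg, Lcp65Ag1 and TwdlP rose in both, TwdlP with q = 0.000429 in the authors' deposited table for smox.

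**Figure D3:**
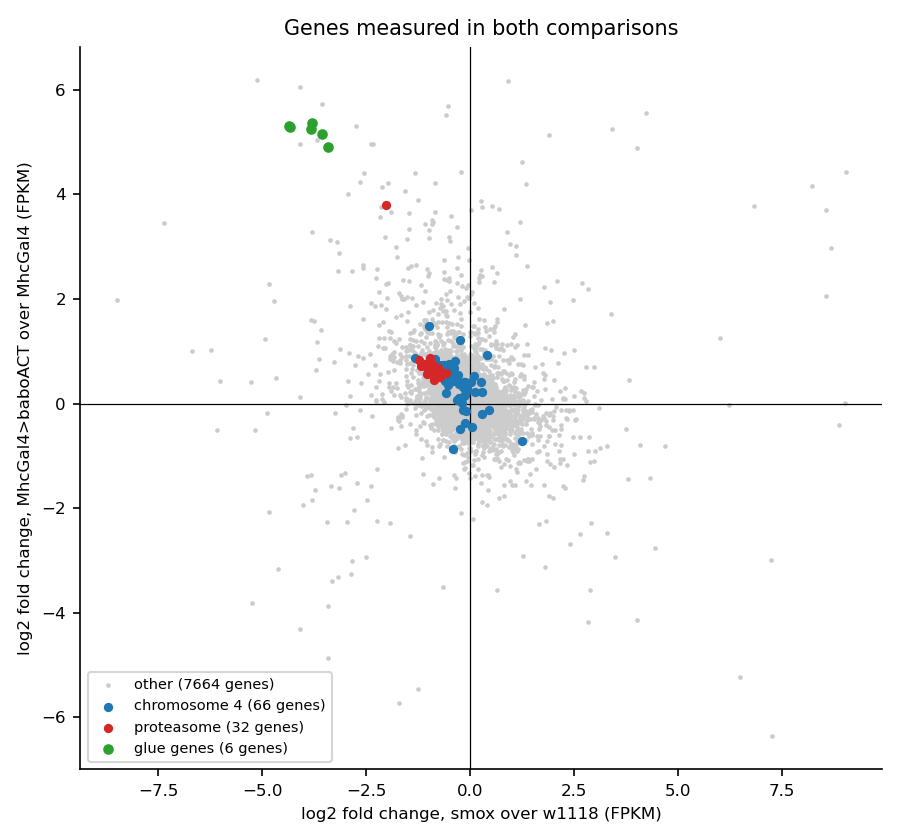
Log2 fold change in smox (horizontal) against log2 fold change with activated Baboon (vertical) for genes measured in both comparisons, 1 point per gene. The 32 proteasome genes (red) and 6 glue genes (green) lie in the upper left quadrant, as do 51 of the 66 genes of chromosome 4 (blue). Gray points are the remaining 7664 genes.

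Because smox larvae were male by genotype and the sex of the larvae in the other 3 groups is not given in the sources used here, X-linked genes were compared with autosomal ones. The median of 1304 X-linked genes in smox was -0.15 against -0.14 for the autosomes and lay within the random range. With activated Baboon 1325 X-linked genes had a median of 0.05 against 0.08, outside on the low side. Dosage compensation evens out X-linked transcripts between the sexes, so these medians cannot show whether the groups differed in sex. The dosage compensation RNA roX1, made in males, stood at 63.9 FPKM in w1118 and 103 FPKM in smox (log2 fold change 0.69). The other such RNA, roX2, stood at 6.23 and 9.30 FPKM (0.58, q = 0.0274 in the authors' deposited table). In MhcGal4 and with activated Baboon roX1 was at 119 and 122 FPKM (q = 0.768 in the authors' deposited table), and roX2 fell from 36.3 to 24.3 FPKM (-0.58). The roX1 levels argue against a group made up of females only, but they do not give the share of males in any group. A difference in sex between smox and w1118 therefore stays possible. Its part in the changes of autosomal genes was not tested, nor was that of any other strain difference.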

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

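The pseudocount of 1, the joint fold threshold for both comparisons and the runs without glue genes, alone or with hormone and cuticle genes, were chosen after the results were seen. No paired analysis was possible because the tables hold 1 value per group and their columns carry no replicate. For the same reason leaving out each library, other splits of the libraries, limma with or without a trend or robust priors, camera with an estimated correlation, and count tools were not run, so whether regrouped libraries would give as many calls is not known. Unknown depth limits statements on genes near 1 FPKM. Asking also for a log2 fold change of at least 1 left 725 of 4638 calls in smox, 506 of 3512 with activated Baboon and 153 of 1938 opposite genes, by the threshold's own construction. Other thresholds and filters gave 3732 to 5086 calls in smox and 3007 to 3970 with activated Baboon. The share of lower genes ranged from 67.4% to 68.4% in smox and from 33.7% to 34.5% with activated Baboon. The opposite share ranged from 70.5% to 81.3%, r from -0.23 to -0.19 and rho from -0.41 to -0.36. Under other scalings and pseudocounts the authors' calls were kept and only directions were recounted. These shares therefore cannot show which genes would be called after rescaling. Median-ratio scaling moves all genes alike and cannot move a list against random lists. The distance of list medians from the random median gained a place outside for proliferation genes in smox without a filter (-0.21), for sarcomere genes in smox at a mean FPKM of at least 5 (0.12), and under quantile normalization for lipid genes (-0.20) and glutathione transferases (0.15) with activated Baboon. It lost one for cytosolic ribosomal proteins with activated Baboon under quantile normalization (-0.050). For these 5 the cause was not tested. The ecdysone and juvenile hormone list in smox reversed without its glue genes, from -0.20 to 0.14 from the random median and inside the range, since those genes made up its low end. No other list outside and no named gene that was called reversed. The log2 fold change of Smox in smox was -3.38 with a pseudocount of 1 and -3.33 under quantile normalization, which adds 1 to each FPKM as well. Among 287 values of named genes, 3, 51 and 53 moved by over 1.5-fold with a pseudocount of 0.1, with one of 1 and under quantile normalization.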

Other observations

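The pigmentation genes, the glue genes and chromosome 4 were singled out after their values were seen, and so were the tests of gland amount on the glue genes and of chromosome 4 copy number. Genes for cuticle pigmentation and tanning, listed after e and ple were seen among the largest rises, differed in part between the experiments. The genes ple, b and yellow-c rose in both. In smox 9 of 16 measured genes rose and 6 fell, with a median log2 fold change of 0.45. Besides e and ple (5.04 to 580 FPKM), yellow-c rose from 15.1 to 108 FPKM, b, which makes beta-alanine, from 17.4 to 112 and Hn, the phenylalanine hydroxylase gene, from 139 to 459. Ddc, the dopa decarboxylase gene, fell from 239 to 135 FPKM and yellow-b from 109 to 38.5. With activated Baboon 9 of 15 rose and 0 fell, with a median of 0.62. There Ddc rose from 21.4 to 400 FPKM, ple from 12.9 to 177 and Pu, the first enzyme of pteridine synthesis, from 39.8 to 141. The genes b (4.35 to 21.6 FPKM) and yellow-c (9.12 to 41.5) rose there too. The gene e stood at 4.66 and 4.67 FPKM and was not called (q = 0.993 in the authors' deposited table). The difference between the experiments was not tested.

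Genes on chromosome 4, the small dot chromosome, shifted as a group in both experiments. In smox 43 of 66 fell and 4 rose, with a median of -0.35 against -0.14 on the large autosomes. With activated Baboon 50 of 67 rose and 5 fell, with a median of 0.50 against 0.08. CG31997 went from 1510 to 608 FPKM in smox and from 449 to 820 FPKM with activated Baboon, and Slip1 from 25.4 to 13.0 and from 13.7 to 38.5 FPKM. Rfabg went the other way, from 12.3 to 29.3 FPKM in smox and from 25.7 to 15.6 FPKM with activated Baboon. Of the other arms, the X chromosome with activated Baboon lay farthest from the autosomal median, at -0.03 from it.

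Locus length and expression level do not account for the chromosome 4 shift. The medians of -0.35 in smox and 0.50 with activated Baboon both lay outside 95% of random lists matched on FPKM and locus length. Locus length is the genomic span of a row and not transcript length, which was not tested. Over 66 genes the Spearman rho between the experiments was -0.65, against a median of -0.36 in random lists of equal size, of which 0.45% lay lower. A shift shared by all genes of the chromosome leaves rho unchanged, so it would not bring this value but is not excluded by it as the source of the medians, and copy number and regulation cannot be told apart. GC content, for which no sequence was used here, and a biological link between Activin signaling and this chromosome stay open too, the last as an untested hypothesis.

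Of 5 other salivary gland genes, chosen after the glue genes were seen, 3 were measured with activated Baboon. There sage rose from 1.30 to 5.09 FPKM, PH4alphaSG2 from 0.267 to 2.35 (q = 0.0226 in the authors' deposited table) and PH4alphaSG1, below the cutoff on mean FPKM, from 0.189 to 1.36 (q = 0.00666 in the authors' deposited table). CrebA stood at 17.3 and 18.8 FPKM and was not called (q = 0.27 in the authors' deposited table). In smox PH4alphaSG2 fell from 2.89 to 0.278 FPKM (q = 0.00767) and CrebA from 16.3 to 11.5, while sage, at 0.872 and 0.388 FPKM, was not called (q = 0.093), with q from the authors' deposited table. The gene fkh stayed below 1 FPKM in all groups and PH4alphaSG1 in both groups of the smox experiment.

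The opposite changes in both experiments could reflect unequal amounts of salivary gland or unequal age of the larvae. Outside the glue genes, the genes lower in smox and higher with activated Baboon carried 38.7 times the FPKM change of the 6 glue genes with activated Baboon and 278 times in smox. These 6 were Sgs3, Sgs4, Sgs5, Sgs7, Sgs8 and Eig71Ee. CG7587, the neighbor of Sgs5, was counted among the others, which may therefore still hold glue genes. A prediction written beforehand took a ratio over 10 as evidence against gland amount, but it assumed that glue dominates the RNA of these glands, whose profile is not measured here, so gland amount and regulation cannot be told apart for those genes. For the glue genes themselves gland amount cannot be told apart from a change within the gland, since only 1 other gland gene (CrebA) reached a mean FPKM of 5. On age, with the glue genes left out, 76.9% of 13 ecdysone-list genes called in both were opposite. The share among other genes was 79.8% (Fisher's exact test, two-sided p = 0.734), and with the glue genes 15 of 18 list genes were opposite. The list is small, and unequal age could make genes outside it opposite too, so similar shares decide nothing. Age and pathway effects cannot be told apart. Without the ecdysone, cuticle and glue genes 79.8% of genes called in both were opposite, a share that age could bring as well.

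Proteasome genes fell together in smox and rose together with activated Baboon. Random lists matched on FPKM and locus length did not reach the medians of -0.92 and 0.63, with 95% of them between -0.22 and 0.05 in smox and between -0.13 and 0.25 with activated Baboon, so these properties do not account for the shift. Under quantile normalization the proteasome medians stayed outside, at -0.82 and 0.57 from the random medians, and GC content and transcript length were not tested. A direct or indirect effect of Activin signaling on transcripts of this complex is an untested hypothesis, found and examined in the same data. The smox mutation was not limited to muscle, so the fall in smox cannot be placed in that tissue.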
